A study of Mus musculus with 4 samples.

How the data were processed

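Total RNA from mouse liver was measured on Affymetrix arrays in 4 wild-type mice of the C57/BL6 background, 1 month old. The titles and the treatment field of the labels place 2 mice in a control group and 2 in a group starved for 24 h, and call the samples of each group biological replicates. The description field instead speaks of mice that were injected or not, so the grouping here follows the titles and the treatment field, and what the injection refers to was not settled. RNA was purified with QIAshredder and RNeasy columns and labelled with the GeneChip IVT kit, per the labels' protocols.

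The deposited values are log2 signals made by the authors with RMA in the affy package, per the submitters' processing notes. The versions of these tools, the background settings and whether the 4 arrays were normalized together or with others are not given in the sources used here. The log2 scale was checked on the values, which lay between 2.83 and 15.5 with medians of 6.71 to 6.74. RMA reports 1 summary signal per probe set and quantile normalization makes the arrays alike in distribution, so a shift common to all transcripts would not be visible. No probe-level signals or detection calls were used, so a low signal is given as a low signal and not as absence.

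The array holds 22690 probe sets, of which 64 Affymetrix controls were left out of every test. Of the others, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none. The last 2 classes were not named here. Symbols were updated through Entrez identifiers in a RefSeq gene table of the mouse assembly GRCm38.p6, which matched 20351 probe sets, and 29 kept the annotation's symbol. Each of 12393 genes was represented by the probe set with the highest mean over all 4 arrays, a rule that does not use the groups. Of these probe sets, 481 end in _x_at and 719 in _s_at, types that may hybridise to related transcripts. Genes measured by _x_at probe sets, and genes of the Cyp4a, Cyp2c, Gstm and other multigene families, are therefore uncertain.

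Starved and control livers were compared with lmFit and eBayes in limma 3.58.1 under R 4.3.3, two-sided, with no covariate. The Benjamini-Hochberg adjustment ran over all 12393 genes, with a threshold of 0.05 on the adjusted p. The prior degrees of freedom were 3.71 and the total 5.71, so most of the information on each gene's spread came from the other genes. The p-values measure the spread between these mice, and the number of arrays limits the precision. The median standard error of a log2 change was 0.133. A permutation test of 2 against 2 arrays cannot give a p below 0.333 and was not used for calls.

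Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01 and the Benjamini-Hochberg adjustment over all 46 lists, and again with a correlation estimated per list. With an estimated correlation, camera takes its degrees of freedom from the residuals of the fit, which are few for these arrays. A call lost in that form is therefore reported without a conclusion on its cause. The lists were drawn from textbook knowledge of fasting metabolism, lysosomes and autophagy, stress and inflammation, growth and housekeeping, 12 cell types that a piece of liver can hold, and sex-biased genes. They name 931 genes, of which 808 were measured. For each list the members past the gene test are counted over all genes and adjusted over the list alone, with the median log2 change. The samples, tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

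The rule names the genes past the test, at most 12 in each direction, whose starved arrays both lay above or both below the control arrays. It also takes up to 4 members of each list with the smallest p, any transcription factor on the list of fasting regulators, reference genes and sex-linked genes. Other genes are named with the remark that they were chosen after their values were seen.

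The alternatives were arrays shifted to a common median, a further quantile normalization, a filter removing the 40% of genes with the lowest mean, the mean of all probe sets per gene, the removal of _x_at and _s_at probe sets, and eBayes with trend and robust settings. A replicate block, each array left out in turn, stricter thresholds of a 2-fold change or an adjusted p of 0.01, all probe sets as the unit of the test, and camera on ranks were also run. The robust and trend settings on their own were added after the data were seen. With 1 array left out, the remaining array of that group is assumed to vary like the other group.

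The tests were checked on simulated arrays with the real means and the fitted spread. With 200 of 12393 genes changed over 20 runs, limma recovered 67.9% of genes changed by 1 log2 unit. It recovered 97.6% of those changed by 2 and 99.4% of those changed by 3, and 5.6% of calls were false. Errors were independent between genes and the sizes of change were set, so these shares do not give the power in the real data. There, 161 genes changed at least 2-fold and 8 passed, and Acot1 (3.62) and Vnn1 (3.08) did not. Camera called a simulated shift of 0.1 in the autophagy list in 40% of runs and a shift of 0.2 in 100%, under errors independent between genes. Figures were drawn with matplotlib 3.10.9.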

Results

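Liver RNA of 4 wild-type mice aged 1 month was profiled on an Affymetrix array with 22690 probe sets. The comparison asks which transcripts differ between livers of 2 mice starved for 24 h and livers of 2 control mice. Values are log2 RMA signals, and a change is the starved mean minus the control mean. Across probe sets, which are not independent replicates, Pearson's r was 0.992 between the control arrays, 0.994 between the starved arrays and 0.986 to 0.991 between groups. By Spearman's rho control 1 was as close to starved 2 (0.9915) as to control 2 (0.9914).

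By the sign of the change, 20 of 22 mitochondrial and 20 of 21 peroxisomal and microsomal genes of fatty acid oxidation were higher in starved liver, and 20 of 20 genes of cholesterol synthesis and 14 of 21 of fatty acid synthesis were lower. Camera called these 4 lists with a preset correlation between genes and 0 of them with an estimated correlation (adjusted p = 0.60 to 0.83). The estimated form has few degrees of freedom, so here and below it cannot tell whether correlation between genes undid a call. Cyp4a14, a microsomal enzyme that hydroxylates fatty acids at the omega end, rose from 6.63 ± 1.33 to 13.99 ± 0.03 (log2, SD, n = 2 per group), a 164-fold difference. Its log2 change of 7.36 was 8.30 without control 1 and 6.42 without control 2. Its relative Cyp4a31 rose 8.22-fold, from control signals of 4.23 and 3.78 that lay below the lower quartile of each array, so the fold is uncertain. Ehhadh, the bifunctional enzyme of peroxisomal beta-oxidation, rose 5.41-fold, and Vnn3, a member of the vanin pantetheinase family, rose 2.89-fold. Nsdhl, a sterol dehydrogenase of cholesterol synthesis, was 6.09-fold lower, with a log2 change of -2.61 ± 0.20 (SE). Cyp2c70, which makes muricholic acids from other bile acids, was 5.94-fold lower, Acly, which supplies cytosolic acetyl-CoA, 2.93-fold lower, and Elovl6, which elongates long-chain fatty acids, 2.77-fold lower.

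These were the 8 genes past the test, 4 higher and 4 lower, each with an adjusted p = 0.0385 in limma. In each the starved arrays lay on the same side of both control arrays. Leaving out any 1 array could therefore not turn the direction of these genes. At an unadjusted p under 0.05 there were 1397 genes, 651 higher and 746 lower, against 620 expected by chance. The groups did not overlap in 42.2% of genes, and chance gives 33.3%. The Cyp4a and Cyp2c probe sets may share signal with related transcripts. Acly was read from an _x_at probe set, and another Acly probe set gave a log2 change of -1.72. With the mean of all probe sets per gene the Acly change was smaller, at -1.33. The count of 8 fell to 0 after a further quantile normalization (adjusted p = 0.0580 for each of the 8 in limma). It was also 0 with the replicate number as a block (adjusted p = 0.10 for each of the 8 in limma). The count came to 27 with trend and robust settings, where Cyp4a14 was the 1 of the 8 not past the test (adjusted p = 0.0864). It was 59 without control 1, 14 without control 2, 2 without starved 1 and 11 without starved 2. Of the 8 genes, 8, 3, 0 and 1 remained past the limma test in these 4 fits, in the same order, and all 8 kept their direction in each.

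**Figure D1:**
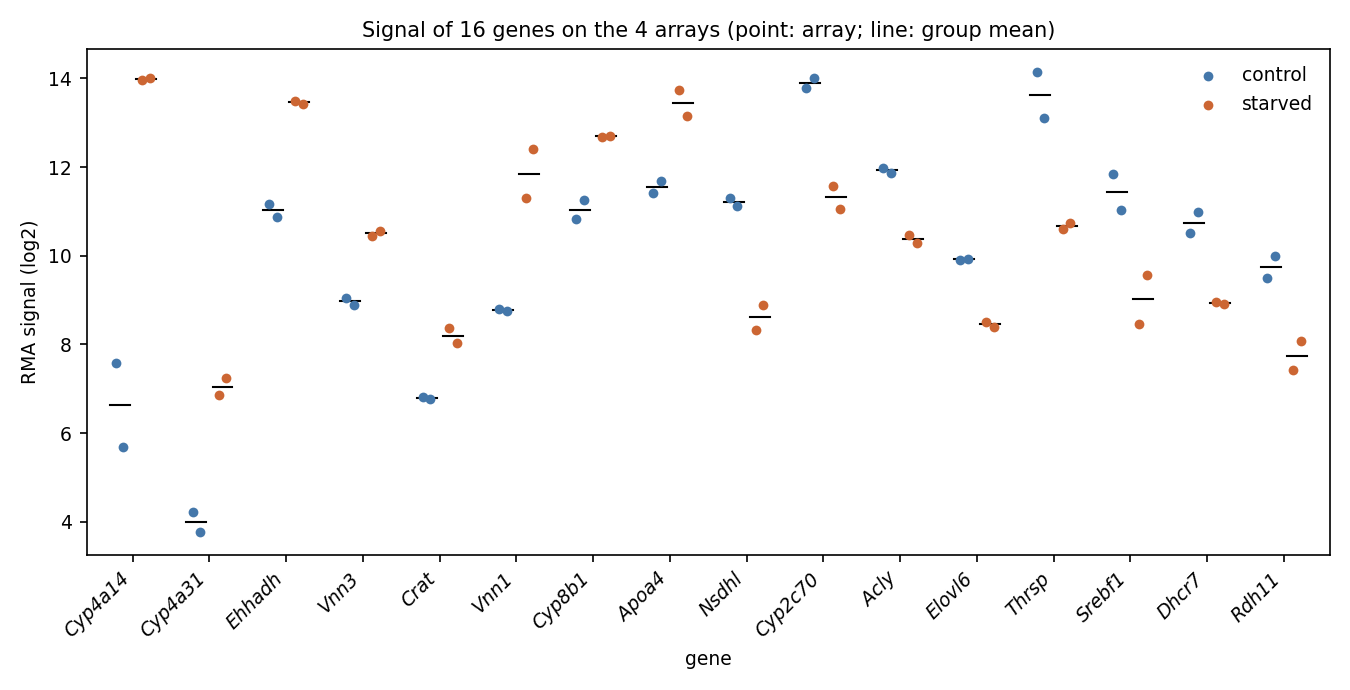
Log2 RMA signal of 16 genes, with each array as a point (blue for 2 control arrays, orange for 2 starved arrays) and each group mean as a line. Cyp4a14 lies at 5.69 and 7.57 on the control arrays and at 13.97 and 14.01 on the starved arrays, and Nsdhl at 11.12 and 11.31 against 8.34 and 8.88.

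Genes of peroxisomal and microsomal fatty acid oxidation rose as a group. Of 21 measured members, 3 rose over all genes tested (Ehhadh, Cyp4a14 and Cyp4a31) and 17 rose when adjusted over the list alone, and the median log2 change was 0.81. Crat, the carnitine acetyltransferase, changed by 1.41 ± 0.15 (SE), which passed over the list alone, and by 0.75 with the mean of all probe sets per gene (adjusted p = 0.156, limma over all genes). Acot1, an acyl-CoA thioesterase chosen after its values were seen, was 12.3-fold higher and also passed over the list alone, with a log2 change of 3.62, or 4.47 without control 1 and 2.77 without control 2. Camera called the list at an adjusted p = 1.07e-18, and the call was lost with an adjusted p = 0.60 with an estimated correlation.

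Target genes of PPAR-alpha, the fatty acid receptor of the fasting liver, also rose. Of 22 measured members, which share 5 genes with the peroxisomal list and 3 with the mitochondrial list, 15 rose when adjusted over the list alone and 2 over all genes, with a median log2 change of 0.92. Vnn1, a pantetheinase, was 8.46-fold higher and Cidec, a lipid droplet protein, 2.31-fold higher, both past the test over the list alone. The camera call had an adjusted p = 5.10e-17, against an adjusted p = 0.60 with an estimated correlation.

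Mitochondrial fatty acid oxidation genes rose by smaller amounts. Of 22 measured members, 14 rose when adjusted over the list alone and 0 over all genes, with a median log2 change of 0.57. Cpt1a, which commits fatty acids to mitochondrial entry, changed by 0.87 ± 0.13 (SE), the carnitine carrier Slc25a20 by 0.94 ± 0.16, Hadhb of the trifunctional protein by 0.93 ± 0.18 and the dienoyl-CoA reductase Decr1 by 0.94 ± 0.18. The camera call had an adjusted p = 2.36e-12, and an adjusted p = 0.83 with an estimated correlation. Of ketone body synthesis, 4 genes were measured and 0 passed the test in either form. Acat1, the mitochondrial acetoacetyl-CoA thiolase, had a log2 change of 0.70 ± 0.22 and Bdh1, the hydroxybutyrate dehydrogenase, of -0.09 ± 0.31, and the list's median was -0.05 (camera, adjusted p = 0.928), or 0.12 without control 2, 0.13 without starved 1 and -0.23 without starved 2.

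Cholesterol synthesis and uptake genes fell together. Of 20 measured members, 19 fell when adjusted over the list alone and 1, Nsdhl, over all genes, with a median log2 change of -1.46. Dhcr7, the last reductase of the pathway, changed by -1.82 ± 0.18 (SE), the cyclase Lss by -1.47 ± 0.14 and the retinol dehydrogenase Rdh11 by -2.00 ± 0.26, all past the test over the list alone. Farnesyl diphosphate synthase, Fdps, chosen after its values were seen, was 10.6-fold lower, with a log2 change of -3.40, or -2.61 without starved 1 and -4.20 without starved 2. With the mean of all probe sets per gene Fdps changed by -1.66 and Lss by -0.83 (adjusted p = 0.114 and 0.117, limma over all genes), and without _x_at and _s_at probe sets Lss changed by -0.89 (adjusted p = 0.208, limma). Camera called the list at an adjusted p = 6.11e-23, and the adjusted p was 0.60 with an estimated correlation. The list's mean, relative to the control mean, was -2.08 on starved 1 and -1.27 on starved 2. The gap between 3′ and 5′ actin probe sets, a sign of RNA integrity, was 2.06 on starved 1 and 1.85 on starved 2, and 1.79 and 1.76 on the control arrays.

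Fatty acid and triglyceride synthesis genes were lower as a group, with exceptions. Of 21 measured members, 2 fell over all genes, Acly and Elovl6, and 6 fell when adjusted over the list alone, while 1 rose. Thrsp, a regulator of lipogenesis, was 7.75-fold lower, Acss2, which activates acetate, 2.04-fold lower, and Srebf1, the transcription factor of lipogenic genes, 5.33-fold lower. The member that rose was Dgat1, which forms triglycerides, with a log2 change of 0.55 ± 0.12 (SE), chosen after its values were seen. The median log2 change was -0.31, and camera called the list at an adjusted p = 3.24e-05, against an adjusted p = 0.60 with an estimated correlation.

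Gluconeogenesis genes moved in both directions. Of 16 measured members, 3 rose and 2 fell when adjusted over the list alone, and 0 passed over all genes. Gpt2, which converts alanine to pyruvate, changed by 0.88 ± 0.11 (SE) and Pcx, the pyruvate carboxylase, by 0.65 ± 0.15. The dicarboxylate carrier Slc25a10, chosen after its values were seen, changed by 0.49 ± 0.14. G6pc, the glucose-6-phosphatase that releases glucose, changed by -1.15 ± 0.23, and the mitochondrial ATP-Mg carrier Slc25a25 by -0.85 ± 0.21. The median log2 change was 0.34, and camera called the list at an adjusted p = 0.0225, against an adjusted p = 0.70 with an estimated correlation. The call was also lost without control 1 (median 0.35, adjusted p = 0.0503), without control 2 (0.18, adjusted p = 0.0643) and without starved 1 (0.24, adjusted p = 0.0570, camera). It was kept with smaller medians for the mean of all probe sets per gene (0.21, adjusted p = 0.0359, camera) and without _x_at and _s_at probe sets (0.20, adjusted p = 0.0377, camera). Glycolysis and hexose use had a median of -0.11 over 14 members (camera, adjusted p = 0.256), or -0.02 without control 1, -0.05 without starved 1 and -0.17 without starved 2. In it Pfkfb3, which makes the activator fructose-2,6-bisphosphate, fell by 1.02 on the log2 scale when adjusted over the list alone.

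Autophagy and lysosome genes showed little shift. Of 36 measured autophagy genes, 0 passed the test over all genes or over the list alone, and the median log2 change was 0.06 (camera, adjusted p = 0.256). Bnip3, a receptor for mitophagy, had the smallest p, with a change of 0.84 ± 0.20 (SE), and Atg7, which activates the conjugation steps of autophagy, had 0.29 ± 0.12. Without starved 2 the list's median was 0.09, with a camera adjusted p = 0.0490. Of 44 lysosome genes, 0 passed in either form, and the median was -0.03 (camera, adjusted p = 0.714). The protease Ctsb changed by -0.40 ± 0.12, and the galactosidase Gla by -0.66 ± 0.12, neither past the test. Pairing each starved array with each control array, the mean of the autophagy list differed by 0.02 to 0.13 and that of the lysosome list by -0.04 to -0.01, against 0.30 to 0.77 for mitochondrial fatty acid oxidation.

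Transcription factors of the fasting response had a median change of 0.18 over 31 members (camera, adjusted p = 0.259), or 0.08 without control 2, 0.10 without starved 1 and 0.10 without starved 2, and 1 of them, Srebf1, fell when adjusted over the list alone, by 2.41 on the log2 scale. Ppargc1a, a coactivator of oxidative and gluconeogenic genes, had a change of 1.01 ± 0.40 (SE), with 9.85 on starved 1 and 8.57 on starved 2. Foxo1, a factor restrained by insulin, had 0.46 ± 0.12, Ppara 0.30 ± 0.18 and Tfeb, a regulator of lysosome and autophagy genes, -0.12 ± 0.12. None of these 4 passed the test.

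**Figure D2:**
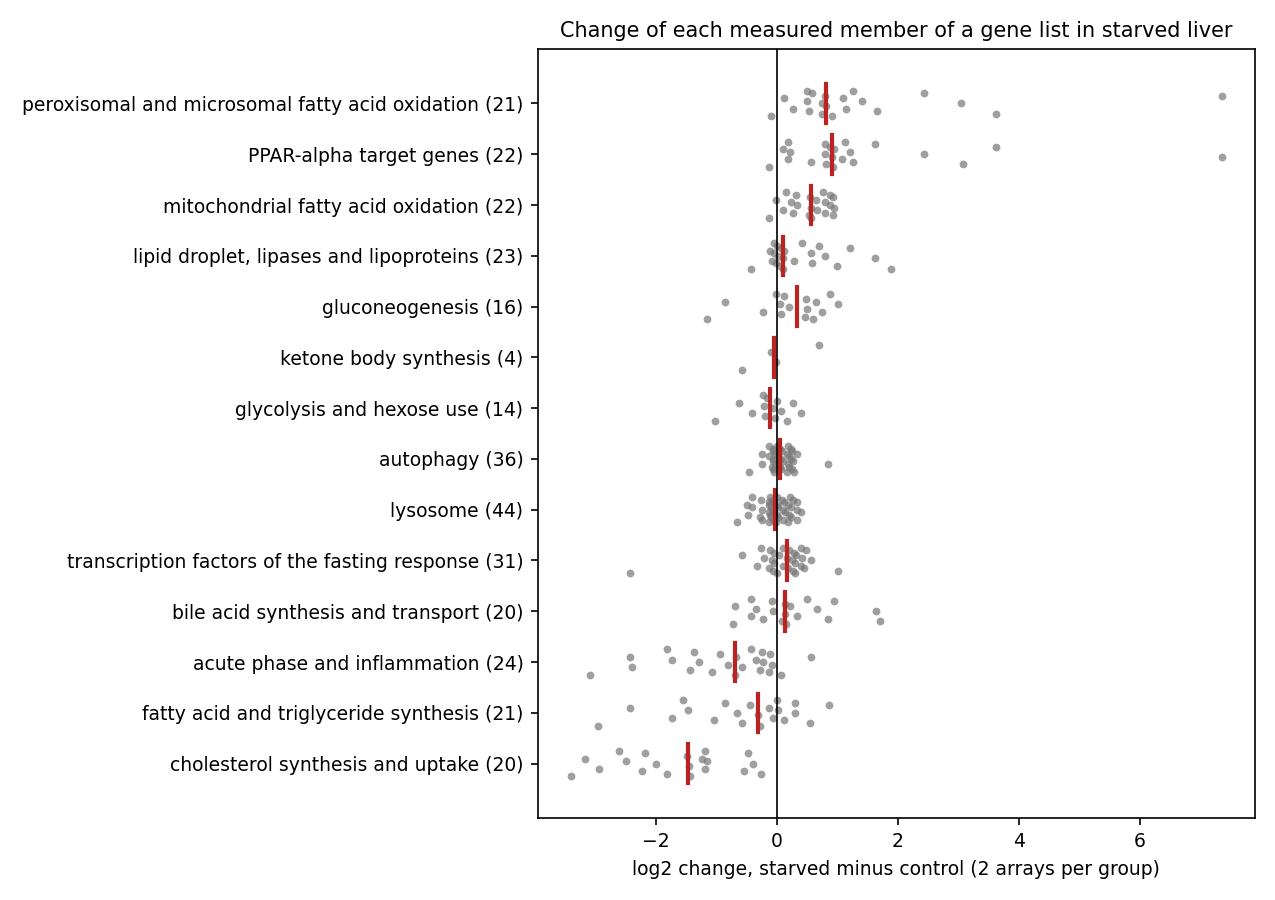
Log2 change, starved minus control, of each measured member of 14 gene lists (grey points, number of members in brackets) with the list's median as a red line. The medians run from 0.92 for PPAR-alpha target genes to -1.46 for cholesterol synthesis and uptake, with autophagy at 0.06 and lysosome at -0.03.

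Lipid droplet, lipase and lipoprotein genes were higher as a group. Of 23 measured members, 4 of them shared with the PPAR-alpha list, 5 rose when adjusted over the list alone and 0 over all genes. Cidec changed by 1.21 ± 0.11 (SE), the apolipoprotein Apoa4, read from an _x_at probe set, by 1.90 ± 0.22, the droplet coat protein Plin5 by 0.99 ± 0.19 and the triglyceride lipase Pnpla2 by 0.80 ± 0.16. The monoglyceride lipase Mgll, chosen after its values were seen, changed by 0.57 ± 0.14. The median log2 change was 0.11, or 0.04 without starved 2, and camera called the list at an adjusted p = 8.92e-04, against an adjusted p = 0.60 with an estimated correlation.

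Bile acid genes split by member. Of 20 measured, 5 rose and 2 fell when adjusted over the list alone, and the median was 0.14 (camera, adjusted p = 0.172), or 0.04 without control 2 and 0.06 without starved 1. Cyp8b1, which forms cholic acid, was 3.14-fold higher, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 3.26-fold higher, and the phospholipid exporter Abcb4 1.81-fold higher. The bile acid receptor Nr1h4 and the oxidase Acox2, both chosen after their values were seen, changed by 0.66 ± 0.19 and 0.50 ± 0.15 (SE). The bile salt export pump Abcb11 changed by -0.69 ± 0.15 and the uptake carrier Slco1a1 by -0.72 ± 0.16. Drug and steroid metabolism genes likewise moved both ways, with 5 of 24 higher and 3 lower when adjusted over the list alone and a median of 0.08 (camera, adjusted p = 0.972), which ran from -0.19 without starved 1 to 0.18 without control 1. The glutathione transferase Gstm3 was 3.30-fold lower and Cyp1a2, which oxidises caffeine, 2.15-fold lower, while Cyp3a11 and the monooxygenase Fmo1 changed by 0.65 ± 0.14 and 0.63 ± 0.14. The Gstm3 change of -1.72 (log2) was -1.05 with the mean of all probe sets per gene (limma, adjusted p = 0.114) and -0.37 without _x_at and _s_at probe sets (limma, adjusted p = 0.466). The other members past the test over the list alone, chosen after their values were seen, were Sult1a1, Nr1i3 and Gsta2, which rose by 0.74, 1.15 and 0.64 (log2), and Gstm1, which fell by 0.44.

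Acute phase and inflammation genes were lower in starved liver. Of 24 measured members, 2 fell when adjusted over the list alone and 0 over all genes. The serum amyloid gene Saa4 changed by -0.93 ± 0.12 (SE), and Hamp, which encodes the iron hormone hepcidin, by -1.28 ± 0.21. The median log2 change was -0.68, and camera called the list at an adjusted p = 1.62e-07, against an adjusted p = 0.83 with an estimated correlation. The control arrays differed, and without control 2 the median was -0.25 (camera, adjusted p = 0.0124). Chosen after their values were seen, Orm2 read 13.79 on control 2 and 9.10 to 9.34 on the other arrays, Lcn2 13.49 against 8.84 to 9.35, and Saa3 12.36 against 8.74 to 8.77.

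**Figure D3:**
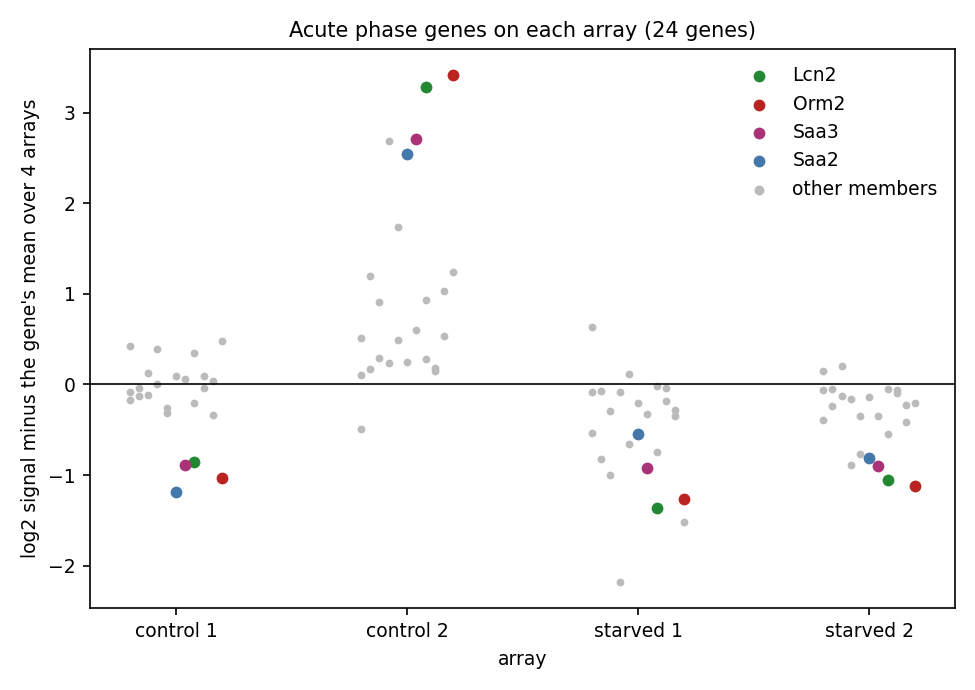
Log2 signal of 24 acute phase genes on each of the 4 arrays, minus the gene's own mean over the arrays, with each gene as a point and Orm2, Lcn2, Saa3 and Saa2 in colour. These 4 genes stand highest on control 2, where Saa2 reads 14.80 against 11.07 on control 1.

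Endoplasmic reticulum chaperones had a median of -0.19 over 20 members (adjusted p = 0.00971, camera; adjusted p = 0.60 with an estimated correlation), and Sec61b of the protein translocon fell by 0.65 when adjusted over the list alone. Without control 1 that list's median was -0.26, with a camera adjusted p = 0.273. Circadian clock genes had a median of 0.33 over 17 members (camera, adjusted p = 0.0104; adjusted p = 0.83 with an estimated correlation), and 0 passed singly, with the repressor Cry1 at 0.88 ± 0.27 (SE). That median was 0.01 without control 2 (adjusted p = 0.267, camera), 0.57 without control 1, and 0.33 without starved 2 (adjusted p = 0.0953, camera), and it was 0.19 with the mean of all probe sets per gene (adjusted p = 0.0189, camera). Female-biased liver genes had a median of 0.12 over 13 members (camera, adjusted p = 0.0240; adjusted p = 0.60 with an estimated correlation), with the thioesterase Acot3, which the peroxisomal list also holds, as the 1 member past the test over the list alone. The call was lost without control 1 (median 0.13, adjusted p = 0.0640, camera) and without _x_at and _s_at probe sets (0.12, adjusted p = 0.0907, camera). The median was 1.24 without the 40% of genes with the lowest mean, which left 4 of the 13 members (camera, adjusted p = 0.0244).

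Across the remaining metabolic and stress lists camera called none. Amino acid breakdown and urea cycle genes had a median of 0.12 (adjusted p = 0.0792), with Asl, the argininosuccinate lyase, at 1.03 ± 0.25 (SE), not past the test. That median was 0.26 without starved 2 (camera, adjusted p = 7.04e-04), 0.19 without control 1 (adjusted p = 0.0503, camera), 0.03 without control 2 (adjusted p = 0.284, camera) and 0.03 without starved 1 (adjusted p = 0.608, camera). The amino acid response list had a median of 0.09, and its factor Atf5 rose by 0.98 when adjusted over the list alone. Growth hormone and insulin signalling had a median of -0.02, with the binding protein Igfbp2 2.38-fold higher and the adipokine Serpina12 2.40-fold lower, both past the test over the list alone. Glucocorticoid-responsive genes had a median of 0.33, and the receptor co-chaperone Fkbp5 was 3.19-fold higher, past the test over the list alone. That list's median was 1.36 without starved 2 (camera, adjusted p = 2.90e-04) and 0.38 without control 2 (adjusted p = 5.38e-04), and -0.04 without control 1 (adjusted p = 0.911, camera). Medians were -0.18 for heat shock proteins, 0.05 for antioxidant defence, 0.11 for immediate early genes and 0.02 for interferon-stimulated genes. Without starved 2, heat shock proteins were called at a median of -0.33 (camera, adjusted p = 0.00155; 0.07 without starved 1, adjusted p = 0.494), and interferon-stimulated genes at -0.23 (adjusted p = 0.00921), whereas without starved 1 the latter were called at 0.31 (adjusted p = 7.64e-05). Cell cycle and DNA replication genes had a median of -0.13, cytosolic ribosomal proteins 0.02, ribosome biogenesis 0.03, proteasome subunits 0.04 and the respiratory chain 0.09. Of these, cell cycle genes were called without control 1 (-0.15, adjusted p = 0.0157), and ribosome biogenesis (0.10, adjusted p = 0.0419) and the respiratory chain (0.14, adjusted p = 0.0145) without starved 2, in camera. Their medians came to -0.03 for the cell cycle without control 2 (adjusted p = 0.859, camera), and to 0.00 for ribosome biogenesis (adjusted p = 0.959, camera) and 0.04 for the respiratory chain (adjusted p = 0.70, camera) without starved 1. The respiratory chain was also called with the mean of all probe sets per gene (0.08, adjusted p = 0.0337, camera) and by camera on ranks (adjusted p = 0.0341).

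Hepatocyte markers had a median change of 0.01 over 15 genes, with 0 past the test. Markers of other cell types had medians of -0.08 for Kupffer cells and macrophages, 0.05 for lymphocytes, -0.04 for neutrophils and 0.18 for erythroid cells. The erythroid median, over 6 genes, was 0.05 without control 2 and 0.30 without control 1. Medians were -0.07 for endothelial cells, -0.08 for stellate cells and fibroblasts, and 0.02 for bile duct cells. Pancreatic acinar markers had 0.00, skeletal muscle -0.08 and intestinal epithelium 0.00. Single members passed the test over the list alone. Lyve1, a hyaluronan receptor of sinusoidal endothelium, changed by 1.81 ± 0.28 (SE), the collagen gene Col3a1 by -1.53 ± 0.25 (-0.84 with the mean of all probe sets per gene), the anion exchanger Slc4a1 of erythroid cells by 0.90 ± 0.18, and the elastase Cela1 by -1.31 ± 0.15. Adipocyte markers were called by camera with a median of 0.18 over 8 genes (adjusted p = 0.0240; adjusted p = 0.60 with an estimated correlation), and the member past the test over the list alone was Cidec. Adiponectin, Adipoq, chosen after its values were seen, read 3.51 to 3.73 on all arrays. The adipocyte call was lost without control 1 (median 0.19, adjusted p = 0.0640), without starved 1 (0.15, adjusted p = 0.0570), without starved 2 (0.27, adjusted p = 0.0651), without the 40% of genes with the lowest mean (0.12, adjusted p = 0.437) and with camera on ranks (adjusted p = 0.0551). Kupffer cell markers were called without control 1 (median -0.25, camera, adjusted p = 0.00274) and had 0.05 without control 2 (adjusted p = 0.457). Stellate cell markers were called without control 2 (-0.31, camera, adjusted p = 3.35e-04) and had 0.20 without control 1 (adjusted p = 0.189). Endothelial markers were called up without control 1 (0.20, adjusted p = 0.0271, camera) and down without control 2 (-0.41, adjusted p = 5.38e-04).

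Of the sex-linked genes, the Y-linked Eif2s3y read 9.27 to 9.91 on the 4 arrays, and Xist, which marks the inactive X of females, 5.48 to 5.83. Their list of 4 genes had a median of -0.16, and was called by camera without starved 2 (-0.34, adjusted p = 0.0145) and had 0.03 without starved 1 (adjusted p = 0.809). Male-biased liver genes had a median of -0.08 (adjusted p = 0.302, camera), or -0.36 without control 1 and -0.31 without starved 2 (adjusted p = 0.0908 and 0.0953, camera), with the steroid dehydrogenase Hsd3b5 at -1.99 ± 0.55 (SE), not past the test, or -1.10 without starved 1 and -2.87 without starved 2. Reference genes had a median of -0.08. Actb fell by 0.62 and Hprt rose by 0.51 when adjusted over the list alone, while B2m had -0.12 ± 0.11 and Gusb -0.06 ± 0.14. The 3′ control probe set for 18S ribosomal RNA read 13.51 and 13.68 on the control arrays and 12.81 and 13.02 on the starved arrays, while the gap between 3′ and 5′ Gapdh probe sets was 0.65 and 0.54 against 0.86 and 0.48.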

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

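The robust and trend settings on their own were chosen after the data were seen. Of the 8 genes past the test, 8 remained past it with arrays shifted to a common median, with the mean of all probe sets per gene and without _x_at and _s_at probe sets. Without the 40% of genes with the lowest mean, Cyp4a31 was not tested and the other 7 remained. Counts of changed, higher and lower genes were 0, 0 and 0 after a further quantile normalization, where the adjusted p of the 8 was 0.0580 in limma and 1414 genes had an unadjusted p under 0.05. They were 27, 10 and 17 with trend and robust eBayes, which held 7 of the 8, all but Cyp4a14 (adjusted p = 0.0864), and 20, 9 and 11 with robust alone. They were 0, 0 and 0 at an adjusted p of 0.01, which is a stricter threshold, and 13, 4 and 9 over all probe sets. For these shifts the cause was not tested, except where the threshold sets it.

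The labels do not say that replicate numbers mark shared litters or days, and the deviations of same-numbered arrays from their group means correlated at 0.017 across genes. With the replicate number as a block the counts were 0, 0 and 0 in limma, with an adjusted p of 0.10 for the 8 genes and 1364 genes at an unadjusted p under 0.05, and camera called 12 lists, the same 12 as without the block. The other 2 splits of the 4 arrays into pairs gave at most 0 genes against the 8 of the real split. In those 2 splits any difference between starved and control widens the spread within each pair, which itself lowers the count. At an unadjusted limma p under 0.05 they gave 346 and 265 genes, against 620 expected by chance. Their 0 is therefore no measure of what chance gives, and 3 splits are too few for a share under 0.05.

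Leaving out 1 array gave 2 to 59 changed, 2 to 23 higher and 0 to 36 lower genes, and 8, 3, 0 and 1 of the 8 genes remained past the test without control 1, control 2, starved 1 and starved 2. The gluconeogenesis median then ran from 0.18 to 0.37 and that of autophagy from 0.014 to 0.093. The median of interferon-stimulated genes ran from -0.23 without starved 2 to 0.31 without starved 1, and that of endothelial markers from -0.41 without control 2 to 0.20 without control 1. Of the 34 lists not called by camera, 21 had a median of either sign over these 4 fits. The cause was not tested. With the mean of all probe sets per gene, smaller changes were found for Fdps (-1.66), Crat (0.75), Lss (-0.83), Gstm3 (-1.05), Col3a1 (-0.84) and Mt1 (1.08), and without _x_at and _s_at probe sets for Gstm3 (-0.37), Lss (-0.89) and Mt1 (0.47).

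Camera with an estimated correlation called 0 of the 46 lists, with a lowest unadjusted p of 0.0519. Estimates lay below the preset 0.01 for the lipid droplet (-0.0089), endoplasmic reticulum chaperone (-0.028), female-biased (-0.037) and adipocyte (-0.118) lists. Their camera p rose too, for lipid droplets from 1.36e-04 to 0.0519. In the other called lists estimates ran from 0.037 to 0.75. Calls were thus also lost without a higher correlation. With few residual degrees of freedom, this form cannot tell whether correlation between genes undid a call. By construction the medians are those found with the preset correlation: 0.57 for mitochondrial and 0.81 for peroxisomal oxidation, 0.92 for PPAR-alpha targets, 0.34 for gluconeogenesis, -0.31 for fatty acid synthesis and -1.46 for cholesterol synthesis. Camera called 11 to 13 lists with the other normalizations, filters, probe set rules and ranks, and 11 to 18 with 1 array left out. The 12 called lists kept their direction in every setting run, but not all of them stayed called. With 1 array left out, calls were lost for gluconeogenesis, endoplasmic reticulum chaperones, the circadian clock, female-biased genes and adipocyte markers. Each of these was lost in at least 1 such fit, and some lists outside the 12 were called instead. No signal over background was used here, so low signals are the least certain, such as those of Cyp4a31 in control liver and most neutrophil markers.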

Other observations

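The tests of explanations in this part were chosen after the results were seen, and so were the genes outside the fixed lists, while the limma test over all genes was planned. Several genes outside the lists had large changes that did not pass the limma test over all genes. Retsat, the retinol saturase, was 5.18-fold higher (adjusted p = 0.0686), the mitochondrial dehydrogenase Hsd17b10 changed by 1.31 ± 0.17 (SE), the galectin Lgals4 by 1.27 ± 0.11 and the acyl-CoA thioesterase Acot12 by 1.15 ± 0.14. The water channel Aqp8 was 4.19-fold lower (adjusted p = 0.0516), the fatty acid binding protein Fabp5 changed by -2.45 ± 0.33, the secreted proteoglycan Prg4 by -1.73 ± 0.19 and the cytokine receptor Lifr by -1.16 ± 0.12. In these 8 genes the starved arrays lay on the same side of both control arrays.

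Some genes stood apart on 1 array. Control 1 read 9.88 for Gdpd3 against 5.36 to 5.52 on the other arrays, 7.86 for the trefoil factor Tff3 against 11.85 to 12.17, and 10.29 for the metallothionein Mt1 against 13.61 to 13.85. Mt1 was read from an _s_at probe set, and its log2 change between groups, 1.70, was 0.47 without _x_at and _s_at probe sets. Starved 2 read 12.81 for the glutathione transferase Gstp3 against 7.52 to 8.16.

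Acute phase genes were higher on control 2 than on control 1 in 23 of 24 members, by a median of 0.56. RMA makes the arrays alike in distribution and so sets the median difference of all genes, -0.030, near 0, which cannot test scale before normalization. In the values used here the quartiles were 5.11 and 8.68 on control 1 and 5.10 and 8.65 on control 2. RMA makes these quartiles alike as well, so they decide nothing on scale as an explanation. They show only that little difference in scale at the quartiles was left in the normalized values. Neutrophils in that sample may contribute and stay open. Their 10 markers had a median difference of 0.26, and S100a9, among the most abundant neutrophil transcripts, read 7.93 on control 2 and 6.29 on control 1, but the median level of the markers, 5.65, lies below the 6.48 under which 40% of genes fall. The design names no difference between the control mice, and no other biological explanation was tested.

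Cholesterol synthesis genes fell less on starved 2 than on starved 1, with 18 of 20 members higher on starved 2 and a median difference of 0.59. A smaller range of all changes on starved 2 would have lowered the PPAR-alpha list there, yet its median difference was 0.25, with 19 of 22 members higher on starved 2. RMA also holds genes of like level near a difference of 0, and the highest median of 10000 random lists of the same size and level was 0.27. That value lies below 0.59, so random lists of like level did not differ as much between the normalized starved arrays. The normalization itself keeps such lists near 0, so no conclusion on a level-dependent difference in scale is drawn. Scale before normalization could not be tested. A difference in RNA integrity may contribute and stays open. The gap between 3′ and 5′ actin signals differed by -0.21 between the starved arrays and by -0.03 between the control arrays. The Gapdh gap differed by -0.38 and -0.11, and positions of the other probe sets were not used here. The labels name no difference between the starved mice, and no biological explanation was tested.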
